A study of Homo sapiens with 4 samples.

How the data were processed

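Total RNA was extracted from SUM159-R cells, transcribed to cDNA with random primers and sequenced on an Illumina NovaSeq6000, per the labels. The data comprise 4 libraries, 1 for each of DMSO, enzastaurin, paclitaxel and the combination; whether a library pooled several cultures is not given in the sources used here. The authors deposited a single table of 20289 Ensembl genes that holds expected counts and FPKM values for each library. Per the labels the authors used RSEM and the hg38 genome; versions, the aligner and the annotation release are not given in the sources used here. The deposited expected counts are not scaled for depth, and 10.7% to 11.4% of the values per library are not whole numbers (tolerance 0), as RSEM writes them. The deposited FPKM values are scaled by the authors for transcript length and library size. The table's column names were matched to the conditions through the treatment names in the labels, and 0 columns remained unmatched.

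Counts were rounded to whole numbers and gave totals of 22576953 for DMSO, 21959564 for enzastaurin, 24699948 for paclitaxel and 18236527 for the combination. The 10 most abundant genes took 8.88%, 8.78%, 8.80% and 8.75% of counts in the same order. TMM factors from edgeR 4.0.16 were 1.000, 1.005, 1.006 and 0.988. A level in CPM, the standard depth-scaled count, was computed from the library total times its TMM factor and has an exact 95% Poisson interval. Symbols are those of the table, which gives none for 583 genes. Coordinates, transcript length and GC content were taken from GENCODE 29, matched by Ensembl ID for 99.0% of the 11843 genes with at least 20 counts in a library.

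With 1 library per condition no p was computed for the 5 contrasts (each single drug over DMSO, and the combination over DMSO, paclitaxel and enzastaurin). No paired analysis was possible because each condition has 1 library. A gene passed the size rule when its TMM-scaled ratio was 2-fold or more, its 95% Clopper-Pearson conditional interval excluded a ratio of 1, and the higher library had at least 20 counts. A count of 0 was set to a floor of 3 counts in that library, which gives a log2 ratio marked as a bound. A fold written as "at least" is the interval end nearest to no change. Intervals and floors cover counting error only, because each condition has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals may understate even that error. On simulated counts with no added spread the rule found 99 of 100 genes changed 2.5-fold and 100 of 100 changed 4-fold, and 23 unchanged genes of 11843 passed it.

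Before the data were examined, 33 gene lists, the contrasts, the alternatives and the rule for naming genes were fixed. That rule took the chromosomal passenger complex, the PKC isozymes and drug transporters with at least 20 counts, the 10 highest and 10 lowest genes by the interval bound nearest to 1 in 3 contrasts, and in each list described the 2 to 4 members past the size rule or the 2 largest. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and called outer under percentile 2.5 or over 97.5. Lists with fewer than 3 measured genes were not ranked, which left 32.

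The additive model of both drugs over the 4 libraries was fitted with edgeR (filterByExpr, glmQLFit, glmQLFTest, Benjamini-Hochberg adjusted p under 0.05), with 2 libraries at each level of each drug, 1 residual degree of freedom, 19.1 prior degrees of freedom and a common biological coefficient of variation of 0.134. Any interaction of the drugs enters its residual spread. On simulated data it found 90 of 100 genes changed 2-fold by paclitaxel and 100 of 100 changed 4-fold, with 12 false calls. The simulated counts had the same spread for every gene, no enzastaurin effect and no interaction, so these rates may not hold for the data. The camera and fry set tests came from limma 3.58.1. DESeq2 1.42.0 gave alternative size factors and a Wald test. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

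Alternatives fixed in advance were DESeq2 size factors, library size alone, no count minimum or one of 100, a fold limit of 1.5, the deposited FPKM values with a pseudocount of 1 or 0.1, no filter on low counts, other tests of the additive model, and random lists without matching. Chosen after the data were seen were thinning of counts to the smallest library, removal of a smooth trend in transcript length and GC content, the subset of genes with a mean of at least 500 counts, and sums over genes that share reads. Sums of shared loci use all deposited counts of the genes named. Leaving out a library was not possible with 1 per condition. Protein data and cell counts are not analysed here.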

Results

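RNA from paclitaxel-resistant SUM159 cells, a human triple-negative breast cancer line written SUM159-R in the labels, was sequenced after 24 h in each of 4 conditions. The cells received DMSO, the protein kinase C (PKC) inhibitor enzastaurin at 2.5 µM, the microtubule-stabilising drug paclitaxel at 500 nM, or both drugs together, called the combination here. The labels state that the resistant line was maintained in 150 nM paclitaxel. Each condition has 1 library, so no level or ratio of conditions below has a replicate error, and every interval is a 95% interval for counting error only. The SE and p of the additive model below rest on its 1 residual degree of freedom and a spread shared across genes. The 4 libraries hold 22576953 counts for DMSO, 21959564 for enzastaurin, 24699948 for paclitaxel and 18236527 for the combination. A count of 0 allows up to 0.133, 0.136, 0.121 and 0.166 CPM in the same order. Genes with at least 20 counts numbered 11576, 11539, 11677 and 11307. The mitochondrial share of counts was 7.08% (7.07 to 7.09, Wilson), 7.12% (7.10 to 7.13), 7.06% (7.05 to 7.07) and 6.70% (6.68 to 6.71).

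The series title speaks of restored Aurora kinase B expression, without saying whether mRNA or protein is meant or against which condition. AURKB mRNA was highest in the DMSO library and lowest in the combination library. AURKB (ENSG00000178999; hg38 chromosome 17, 8204733 to 8210600, minus strand) encodes the kinase of the chromosomal passenger complex, which corrects chromosome attachments and drives cytokinesis. Its level was 31.2 CPM (28.96 to 33.6) in DMSO, 26.1 CPM (24.0 to 28.4) in enzastaurin, 24.5 CPM (22.6 to 26.6) in paclitaxel and 20.9 CPM (18.9 to 23.1) in the combination. The deposited FPKM values of AURKB were 28.3, 23.17, 21.3 and 17.75 in the same order. On the log2 scale AURKB was -0.26 (-0.42 to -0.10) in enzastaurin over DMSO, -0.35 (-0.51 to -0.19) in paclitaxel over DMSO, -0.58 (-0.76 to -0.40) in combination over DMSO and -0.23 (-0.42 to -0.04) in combination over paclitaxel. None of these AURKB differences reached 2-fold, and with 1 culture each they cannot be set against the spread between cultures. Only mRNA was measured, so Aurora B protein and kinase activity are outside these values.

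Of the other passenger subunits, INCENP was lower in the combination than in paclitaxel, as AURKB was, while BIRC5 and CDCA8 were not. INCENP (chromosome 11, 62123973 to 62153163), the scaffold that activates the kinase, had 2319, 2371, 2140 and 594 counts in DMSO, enzastaurin, paclitaxel and the combination, with a log2 ratio of -1.39 (-1.52 to -1.25) in combination over paclitaxel. BIRC5 (chromosome 17, 78214186 to 78225636), which encodes survivin, was at 136, 131, 126 and 190 CPM, with a log2 ratio of 0.59 (0.52 to 0.66) in the same contrast. CDCA8 (chromosome 1, 37692418 to 37709719), which encodes borealin, had 1971, 1922, 1989 and 1568 counts, with a log2 ratio of 0.12.

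Of the PKC isozymes, the target family of enzastaurin, PRKCA (chromosome 17, 66302636 to 66810743) had the most counts, at 207, 219, 206 and 186 CPM. PRKCB, the isozyme against which enzastaurin was developed, had 0 counts in the first 3 libraries and 2 in the combination. The other 8 measured members of the PKC and PKD families (PRKCD, PRKCE, PRKCH, PRKCI, PRKCZ, PRKD1, PRKD2 and PRKD3) stayed under 2-fold in every contrast, and the lowest value was PRKCD at -0.75 (-0.89 to -0.60) in combination over DMSO. ABCB1 (chromosome 7, 87503633 to 87713323), the efflux pump for which paclitaxel is a substrate, was at 288, 329, 354 and 447 CPM. Its log2 ratio was 0.30 (0.25 to 0.35) in paclitaxel over DMSO and 0.33 (0.29 to 0.38) in combination over paclitaxel. Of the other 8 measured transporters, ABCC1, ABCC3, ABCC4, ABCC5, ABCC10 and ABCG2 lay between -0.32 and 0.28 in all 5 contrasts, while ABCC2 was at -0.66 (-0.74 to -0.59) and ABCB4 at -0.74 (-1.04 to -0.44) in combination over enzastaurin.

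Enzastaurin over DMSO asks what enzastaurin at 2.5 µM did in the resistant line without added paclitaxel. PKC activity was not measured, and whether the maintenance paclitaxel was withdrawn is not given in the sources used here. Of the immediate early and ERK-induced genes, FOSB was at -0.91 (-1.33 to -0.49) and MYC at -0.34 (-0.39 to -0.30) on the log2 scale. The ERK phosphatase genes DUSP5, at -0.65 (-0.81 to -0.49), and DUSP6, at -0.59 (-0.78 to -0.40), were lower as well. CDKN1A, which encodes p21, was at -0.28 (-0.41 to -0.15). The antioxidant genes SLC7A11, at 0.45 (0.40 to 0.51), and HMOX1, at 0.41 (0.32 to 0.50), were higher, as were HMGCS1, at 0.25 (0.19 to 0.32), and STARD4, at 0.28 (0.15 to 0.41), of the cholesterol list.

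These differences were small: 105 of 11843 genes differed by 2-fold or more beyond counting error, 52 higher and 53 lower. Medians of the gene lists were compared with 10000 random lists matched on expression, which describes these libraries and is not a p. The median of the 19 measured AP-1 and immediate early genes was -0.25 (percentile 0), that of 14 ERK feedback genes -0.18 (percentile 0), and that of 12 senescence secretome genes -0.26 (percentile 0.15). The median of 14 NRF2 targets was 0.09 (percentile 99.8), and that of 18 cholesterol synthesis genes was 0.08 (percentile 99.4). No member of these 5 lists passed the 2-fold rule in this contrast. The ribosomal protein list had a median of -0.06 (percentile 0.29), led by RPL13 at -0.15 and RPL3 at -0.09. The folds of this contrast followed transcript length (Spearman 0.345 across 6974 genes) and GC content (Spearman -0.532); with that trend removed the ribosomal list moved to percentile 47.5 and the other 5 lists stayed in the outer 5%. Without matching on expression the NRF2 list moved to percentile 97.3, and with the deposited FPKM values the AP-1 list moved to 3.12.

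Most genes with the largest enzastaurin ratios share their reads with a neighbour or paralog, so their individual values are uncertain. The 10 highest were SMIM11A, RGPD6, TVP23C-CDRT4, FREM2, CORO7-PAM16, P3R3URF-PIK3R3, CEMP1, ZFP91-CNTF, LHX8 and CSTA, and 6 of them are readthrough genes or near-identical copies. The 10 lowest were INO80B-WBP1, CDRT4, H4C11, SPECC1L-ADORA2A, SMIM11B, CCDC103, COMMD3-BMI1, CLEC11A, C8orf44-SGK3 and AMY1C, of which at least 7 are of that kind. SMIM11A had 15 counts in DMSO and 284 in enzastaurin while its copy SMIM11B had 314 and 41, and the sum of both differed by 0.01 (-0.21 to 0.24) on the log2 scale. RGPD6 was at 4.04 (3.20 to 5.02), but RGPD5 and RGPD6 summed were at 0.04. Among genes for which no such partner was listed, FREM2, a basement membrane protein gene, had 0 counts in DMSO and 26 in enzastaurin, at least 6.71-fold higher. FREM2 was again higher in combination over paclitaxel at 3.92 (1.90 to 7.06). LHX8 and CSTA, with 4 and 24 counts each, were both at 2.62 (1.08 to 4.60) in enzastaurin over DMSO, and at 0.62 (-0.84 to 2.09) and 0.05 (-1.16 to 1.22) in combination over paclitaxel. CCDC103 was at -2.87 (-4.84 to -1.37) and CLEC11A at -3.29 (-6.43 to -1.25), from 20 to 30 counts in DMSO. Neither was summed with a neighbouring gene, so a shift of shared reads is not excluded for them.

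Paclitaxel over DMSO asks how resistant cells responded to 500 nM paclitaxel against none added; whether the maintenance paclitaxel was withdrawn for the DMSO cells is not given in the sources used here. Oxidative stress genes were higher: HMOX1 (chromosome 22, 35380361 to 35394214), the haem-degrading enzyme and an NRF2 target, was 2.52-fold higher, at 1.33 (1.25 to 1.41) on the log2 scale. The aldo-keto reductase genes AKR1C1, AKR1C2 and AKR1C3, near-identical NRF2 targets, summed to 4080, 5381, 9617 and 11445 counts in DMSO, enzastaurin, paclitaxel and the combination, a log2 ratio of 1.10 in paclitaxel over DMSO. IL24, a cytokine gene, was at 2.16 (1.32 to 3.11), BCL2L11, which encodes the pro-apoptotic BIM, at 1.12 (0.71 to 1.54), and the chemokine gene CCL20 at 1.24 (0.72 to 1.77). Lower were the carboxypeptidase gene CPA4, at -1.11 (-1.24 to -0.98), and the YAP targets CCN1, at -0.66 (-0.71 to -0.60), and AXL, at -0.47 (-0.51 to -0.42).

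In this contrast 147 genes passed the 2-fold rule, 96 higher and 51 lower. The NRF2 list had a median of 0.28 (percentile 100), with HMOX1 and AKR1C1 past the rule. The 22 S phase genes had a median of -0.13 (percentile 0) with no positive member, and GINS2, at -0.42 (-0.57 to -0.27), and MCM5, at -0.26 (-0.33 to -0.20), were its largest. The chromosomal passenger list had a median of -0.19 (percentile 0.26), and the YAP list of 12 genes one of -0.15 (percentile 0). Of 7 measured replication-dependent histone genes 4 passed the rule upward, with H2BC21 at 1.72 (1.03 to 2.48), H2BC4 at 1.54 (0.68 to 2.48), H2BC5 at 1.51 (0.67 to 2.42) and H2AC6 at 1.13 (0.62 to 1.65), all from low counts. The FOXO list (median 0.23, percentile 100) had BCL2L11 and SESN3, at 1.10 (0.58 to 1.63), past the rule. The senescence secretome list (median 0.47, percentile 100) had IL1A, at 1.03 (0.41 to 1.68), past it, with AREG at 0.75 (0.40 to 1.11). The NF-kB list (median 0.13, percentile 99.6) had CCL20 and IL1A past it.

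Smaller shifts with paclitaxel were seen in the stress response list (median 0.09, percentile 98.6), with DDIT3 at 0.81 (0.43 to 1.20) and SLC7A11 at 0.46 (0.40 to 0.51). The heat shock list had a median of 0.09 (percentile 99.2), with HSPH1 at 0.21 and HSPA8 at 0.19, and the transporter list one of 0.10 (percentile 98.5). The TGF-beta list had a median of 0.08 (percentile 98.0) but a mean of -0.001, with COL1A1 at -0.45 and SKIL at 0.35. The cholesterol list had a median of -0.10 (percentile 0.11), with INSIG1 at -0.31 and MVD at -0.34. The AP-1 list had a median of -0.09 (percentile 1.00) but a mean of 0.08, with EGR2 at 2.32 (0.76 to 4.32) and JUND at -0.67 (-0.81 to -0.53). Folds followed GC content here too (Spearman -0.391) and length more weakly (0.140). With that trend removed the AP-1 list moved to percentile 15.8 and the transporter list to 91.7, and with the deposited FPKM values the NF-kB, stress response and TGF-beta lists moved to 92.0, 95.8 and 91.3. Without matching on expression the heat shock and passenger complex lists moved to percentiles 94.7 and 2.95.

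The 10 highest genes in paclitaxel over DMSO were RGPD6, SMIM11A, H2AC18, TVP23C-CDRT4, TGIF2-RAB5IF, P3R3URF-PIK3R3, RPL36A-HNRNPH2, AMY1B, IL24 and HMOX1, of which 8 share reads with a copy or a readthrough partner. The 10 lowest were PDCD6-AHRR, INO80B-WBP1, CDRT4, NPIPA3, SMIM11B, SAPCD1, SLX1B, GALNT4, UPK3BL1 and EIF3CL, of which at least 7 do. H2AC18 had 0 counts without paclitaxel and 45 and 52 counts with it, at least 10.6-fold higher in paclitaxel over DMSO, while H2AC18 and its copy H2AC19 summed were at 0.73. In combination over enzastaurin, which shares no library with this contrast, HMOX1 was at 1.69 (1.62 to 1.76), and IL24 at 2.06 (0.56 to 3.85). EIF3CL was at -1.32 (-1.83 to -0.84) there, but EIF3C and EIF3CL summed were at 0.03. Also higher in combination over enzastaurin were RGPD6 at 2.27 (2.04 to 2.50), H2AC18 at 4.41 (a bound) and RPL36A-HNRNPH2 at 1.11 (0.56 to 1.69). Also lower were UPK3BL1 at -2.93 (a bound), SAPCD1 at -1.71 (-2.95 to -0.63) and PDCD6-AHRR at -0.998 (-1.583 to -0.439). Summed with their copies or partners, RGPD6 was at 0.13, H2AC18 at 0.72 and the PDCD6-AHRR locus at 0.02. UPK3BL1, SAPCD1 and RPL36A-HNRNPH2 were not summed with any other gene, so a shift of shared reads is not excluded for them. The rest were near 0 or on the opposite side. These included SLX1B at 0.03, AMY1B at -0.21, NPIPA3 at -0.25, GALNT4 at 0.71 and SMIM11A at -4.40. SMIM11B, CDRT4, TVP23C-CDRT4, INO80B-WBP1 and P3R3URF-PIK3R3 were also opposite, and TGIF2-RAB5IF was at -0.39.

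Combination over paclitaxel asks what enzastaurin added in paclitaxel-treated cells, and here the genes of mitosis moved apart. Some were higher without passing the 2-fold rule: CCNB1 (cyclin B1; chromosome 5, 69167010 to 69178245) at 1.00 (0.96 to 1.04), CDC20, the activator of the anaphase-promoting complex, at 0.94 (0.89 to 0.98), AURKA at 0.93 (0.86 to 0.99), and PLK1 at 0.70. These were chosen after their values were seen, as were KIF20A, at 0.84 (0.78 to 0.89), and CKS2, which passed the rule at 1.09 (1.00 to 1.18). Other genes of the same lists were several-fold lower. TOP2A (topoisomerase II alpha; chromosome 17, 40388516 to 40417950) was at -2.17 (-2.23 to -2.10), CDK1 (the partner kinase of cyclin B1; chromosome 10, 60778331 to 60794852) at -1.98 (-2.10 to -1.86), UBE2C at -1.62 (-1.81 to -1.43), and CDC25C at -1.48 (-1.87 to -1.10). TOP2A levels were 668, 692, 555 and 124 CPM in DMSO, enzastaurin, paclitaxel and the combination, and those of CCNB1 were 339, 352, 387 and 774 CPM.

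**Figure D1:**
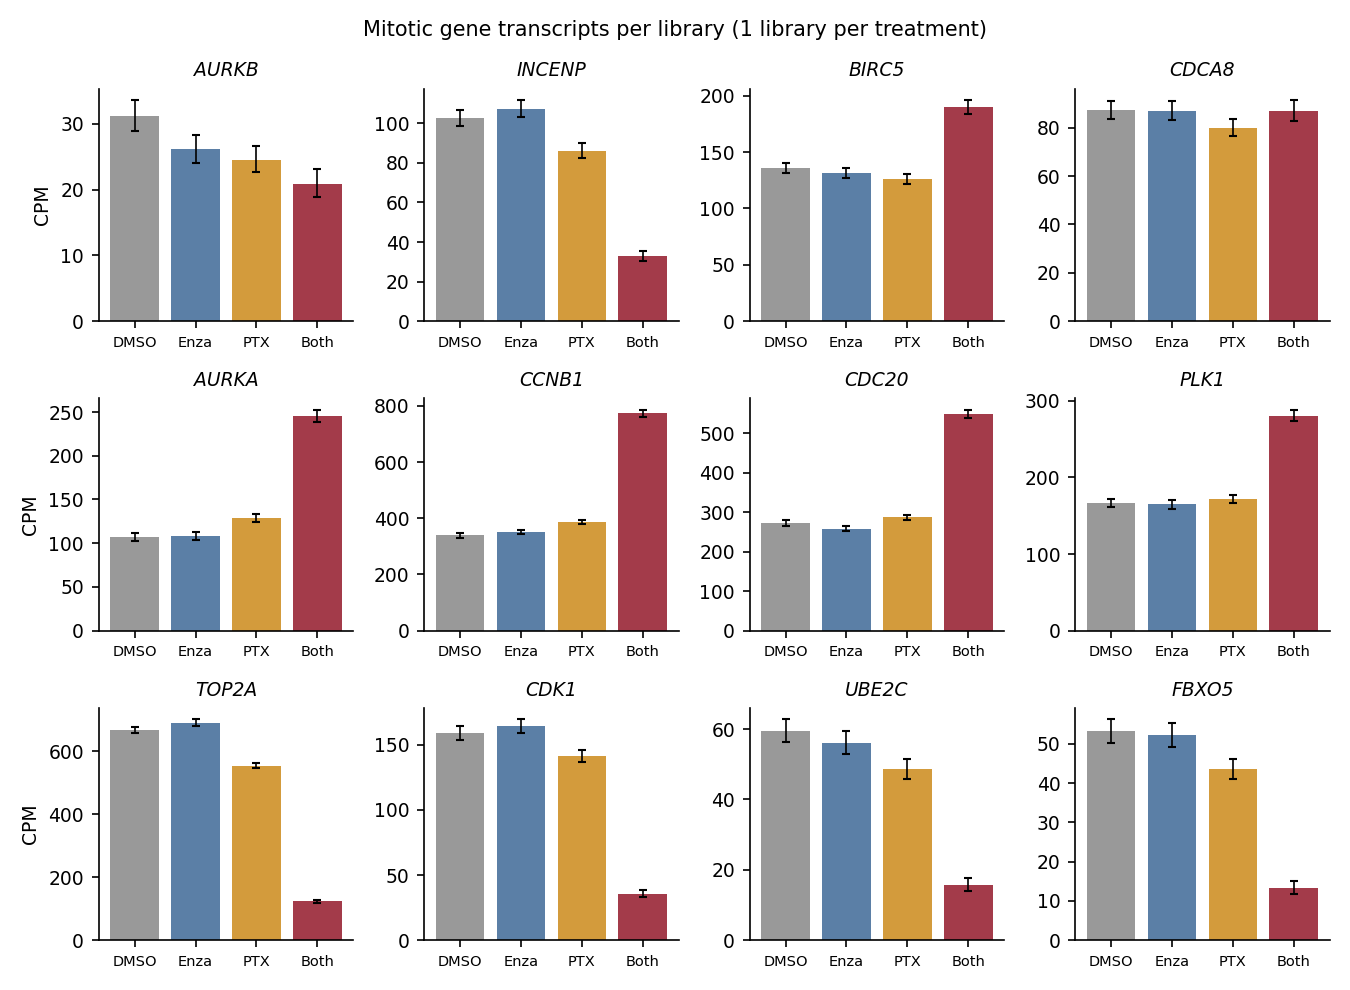
Levels of 12 genes in CPM, with a linear axis from 0, in the DMSO, enzastaurin (Enza), paclitaxel (PTX) and combination (Both) libraries; bars are single libraries and error bars are exact 95% Poisson intervals, and the genes were picked after their values were seen. CCNB1 reached 774 CPM and TOP2A 124 CPM in the combination, against 387 and 555 CPM in paclitaxel.

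In combination over paclitaxel 562 genes passed the 2-fold rule, 68 higher and 494 lower. The mitotic entry list of 22 genes had a median of 0.33 (percentile 100) but a mean of -0.05, because TOP2A, CDK1, UBE2C and CDC25C passed the rule downward and no member passed it upward. The spindle checkpoint list of 19 genes had a median of 0.20 (percentile 99.4), with CDC20 highest and BUB3 lowest, at -0.93 (-1.01 to -0.85). All 22 S phase genes were negative, with a median of -0.54 (percentile 0), and the cyclin E genes CCNE2, at -1.68 (-1.93 to -1.44), and CCNE1, at -1.33 (-1.70 to -0.98), passed the rule. The histone list had a median of 0.63 (percentile 99.9), with H2BC21 at 0.86 (0.42 to 1.29) and H2BC5 at 0.95. With the deposited FPKM values the spindle checkpoint list moved to percentile 91.2.

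YAP targets and AP-1 genes had low medians in the same contrast. The YAP and TEAD list had a median of -0.53 (percentile 0), with CCN1 (chromosome 1, 85580761 to 85583962) at -1.89 (-1.98 to -1.79), CCN2 at -1.61 (-1.75 to -1.48), AMOTL2 at -1.30 (-1.39 to -1.21) and ANKRD1 at -1.17 (-1.83 to -0.55). The AP-1 list had a median of -0.47 (percentile 0), with 6 of 19 members past the rule downward and 1 upward. Those lower included JUND at -1.66 (-1.92 to -1.42), ZFP36 at -1.30 (-1.47 to -1.13), KLF6 at -1.12 (-1.21 to -1.03) and KLF2 at -1.98 (-3.19 to -0.94), and the member higher was EGR2 at 1.56 (0.80 to 2.36). The TGF-beta list (median -0.26, percentile 1.27) had CCN2 and PMEPA1, at -1.27 (-1.58 to -0.96), past the rule, and the FOXO list (median -0.48, percentile 0.66) had INSR, the insulin receptor gene, at -1.68 (-2.02 to -1.36). The ERK feedback list had a median of -0.15 (percentile 2.43), with DUSP6 at -0.71 (-0.88 to -0.53) and SPRY2 at -0.60 (-0.72 to -0.48). With the length and GC trend removed, the TGF-beta, FOXO and ERK feedback lists moved to percentiles 6.59, 5.25 and 4.05.

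NRF2 targets and heat shock genes had high medians in combination over paclitaxel, while the integrated stress and unfolded protein response list did not (median 0.08, percentile 81.3). The NRF2 list had a median of 0.38 (percentile 100) with 13 of 14 members positive and none past the 2-fold rule, and HMOX1 was at 0.76 (0.71 to 0.82) and the summed AKR1C genes at 0.71. The heat shock list had a median of 0.47 (percentile 100), with HSPH1 at 0.76 (0.71 to 0.81), while the paralog pair HSPA1A and HSPA1B summed to -0.35. The ribosomal protein list had a median of 0.26 (percentile 99.9), with RPS19 at 0.34, and it moved to percentile 49.1 with the length and GC trend removed (Spearman of this contrast with length -0.289, with GC -0.0353).

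**Figure D2:**
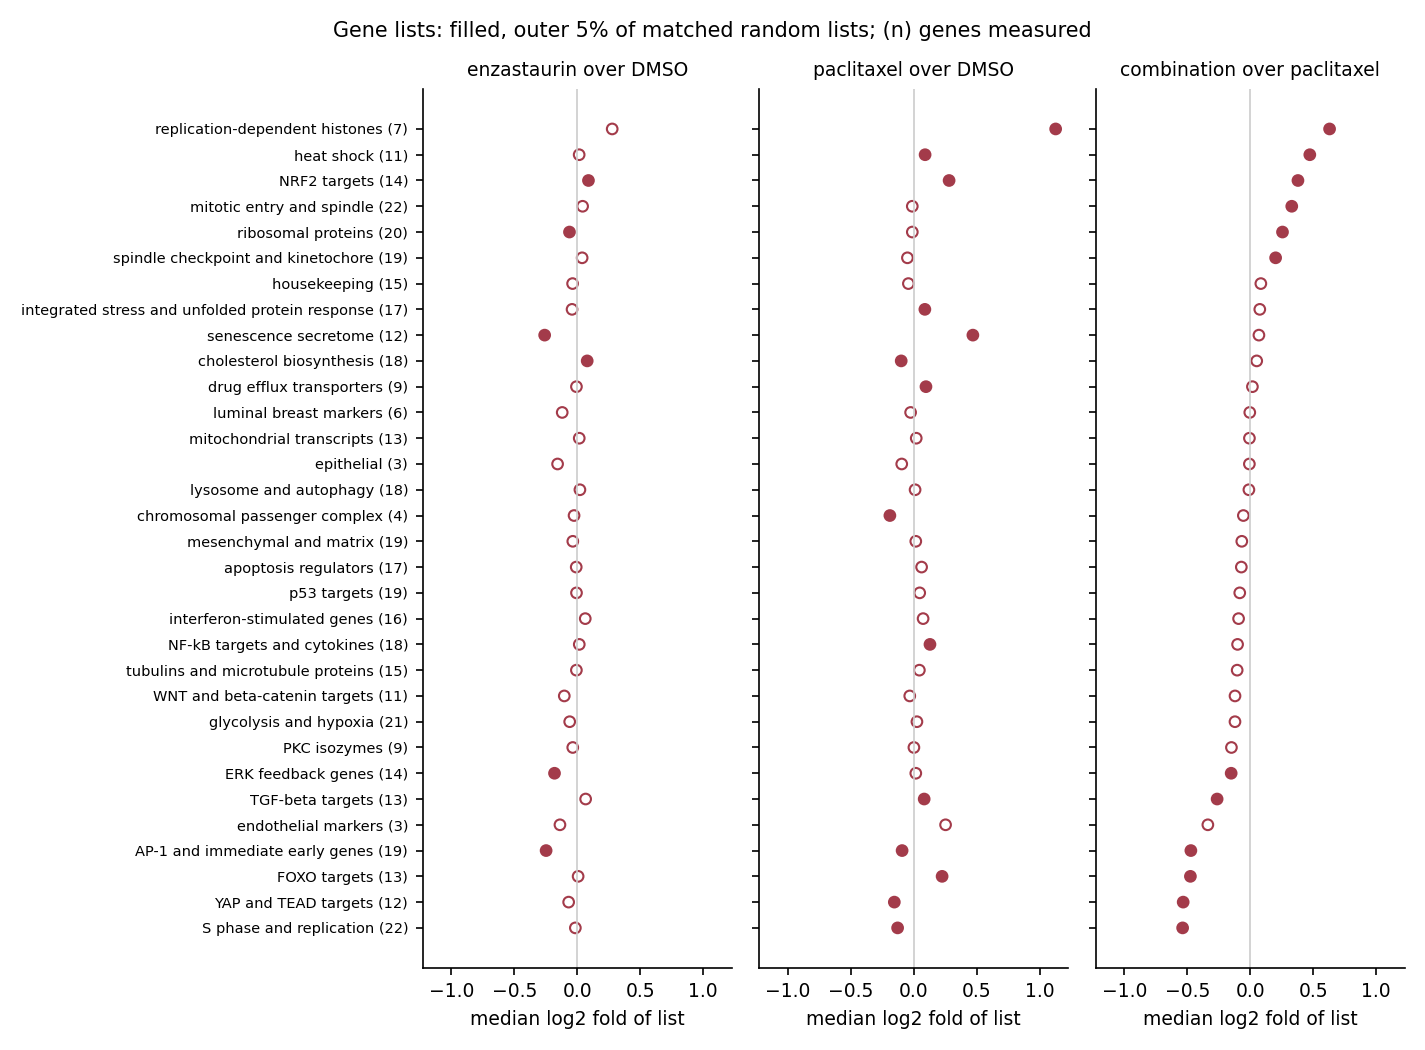
Median log2 ratio of each gene list in enzastaurin over DMSO, paclitaxel over DMSO and combination over paclitaxel, on a log2 axis, with the number of measured genes beside each name; filled points lie in the outer 5% of 10000 expression-matched random lists. The S phase list lies at -0.13 in paclitaxel over DMSO and -0.54 in combination over paclitaxel, and the NRF2 list at 0.28 and 0.38.

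The 10 genes lowest in combination over paclitaxel were SMIM11A, POC1B-GALNT4, CHURC1-FNTB, TOP2A, P3R3URF-PIK3R3, CPA4, ZBED6, CDK1, CCN1 and FLOT2. Of these, 5 share reads with a partner; ZBED6 lies in an intron of ZC3H11A, and their sum was at -0.26. CPA4 (chromosome 7, 130293134 to 130324180) was at -2.36 (-2.67 to -2.05) and FLOT2, a lipid raft protein gene (chromosome 17, 28879335 to 28897679), at -1.94 (-2.09 to -1.79), each from at least 713 counts in paclitaxel. Among those without a partner, values in enzastaurin over DMSO were TOP2A at 0.05 (0.02 to 0.08), CDK1 at 0.05 (-0.02 to 0.11), CPA4 at -0.21 (-0.33 to -0.10), CCN1 at -0.23 (-0.28 to -0.18) and FLOT2 at -0.17 (-0.25 to -0.09). The 10 highest were INO80B-WBP1, PDCD6-AHRR, CDRT4, H4C15, GALNT4, SMIM11B, SLX1B, TBC1D3I, FREM2 and NPIPA3. Of these, at least 6 share reads and 8 have under 100 counts in every library. Only readthrough genes and genes with a listed copy or partner were counted as sharing reads. Members of gene families that were not listed, such as H4C15, TBC1D3I and NPIPA3, may share reads too.

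Combination over DMSO compares both drugs with neither, and combination over enzastaurin compares enzastaurin-treated cells with and without paclitaxel. HMOX1 was at 2.09 (2.02 to 2.17) over DMSO, CPA4 at -3.47 (-3.77 to -3.17), TOP2A at -2.43 (-2.50 to -2.37) and CCN1 at -2.54 (-2.64 to -2.45). Of the senescence secretome list, MMP3, at 2.91 (1.53 to 4.63), GDF15, at 2.38 (1.15 to 3.81), IL1A, at 1.78 (1.19 to 2.42), and MMP1, at 1.59 (0.85 to 2.38), were higher over DMSO. Of 15 measured tubulin and microtubule genes 3 passed the rule downward over DMSO and 0 upward, with MAP1B at -1.40 (-1.49 to -1.32), TUBB at -1.11 (-1.13 to -1.08) and TUBA1C at -1.06 (-1.10 to -1.03). Over DMSO 775 genes passed the 2-fold rule, 120 higher and 655 lower, and over enzastaurin 753 did, 110 higher and 643 lower. Of the 655 lower over DMSO, 621 passed the rule with neither drug alone.

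The same 11 lists lay in the outer 5% in both contrasts. Over DMSO the medians were 0.36 for mitotic entry (percentile 100, mean -0.07), 0.26 for the spindle checkpoint (percentile 99.7), -0.62 for S phase (percentile 0), 1.49 for histones, 0.67 for NRF2, 0.53 for heat shock, -0.56 for AP-1 and -0.61 for YAP. The tubulin list was at -0.24 (percentile 0.435, or 6.06 without matching on expression), the senescence secretome list at 0.28 (percentile 98.8) and the ribosomal list at 0.26 (percentile 99.7). Over enzastaurin the medians were 0.29 for mitotic entry, 0.22 for the spindle checkpoint, -0.61 for S phase, 1.59 for histones, 0.55 for NRF2, 0.52 for heat shock, -0.49 for AP-1, -0.71 for YAP, 0.66 for the senescence secretome, 0.29 for ribosomal proteins and -0.15 for tubulins (percentile 2.39, or 16.2 without matching and 16.1 with the length and GC trend removed). With that trend removed the spindle checkpoint list moved to percentiles 95.9 and 96.7 in these contrasts, the ribosomal list to 74.9 and 46.5, and the senescence list over DMSO to 97.1.

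Across all 5 contrasts, 54 of 160 pairs of list and contrast lay in the outer 5% of matched random lists. For lists of unrelated genes, 1.6 of the 32 lists in each contrast would be expected there. Genes of a list can move together and the 5 contrasts reuse 4 libraries, so this expectation is not a chance rate for these pairs. Lists in the middle 95% in every contrast covered p53 targets (19 measured), apoptosis regulators (17), PKC isozymes (9), WNT targets (11), interferon-stimulated genes (16), glycolysis and hypoxia (21), mesenchymal and matrix genes (19), lysosome and autophagy (18), mitochondrial transcripts (13) and housekeeping genes (15). The same held for markers of other cells, with 3 measured epithelial, 3 endothelial and 6 luminal genes. Of the immune cell markers only CD68 was measured, at -0.49 (-0.71 to -0.27) in enzastaurin over DMSO.

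The layout of 2 drugs allowed a single test, an additive edgeR quasi-likelihood model over the 4 libraries, which leaves 1 residual degree of freedom. Averaged over both enzastaurin states, paclitaxel raised 9 genes and lowered 18 of 12129. HMOX1 rose by 1.52 (SE 0.147, adjusted p = 1.587e-05), AKR1C2 by 1.43 (SE 0.142, adjusted p = 1.587e-05) and AKR1C1 by 1.27 (SE 0.168, adjusted p = 0.000641) on the log2 scale, each higher in both paclitaxel libraries than in the 2 without it. CPA4 changed by -2.07 (SE 0.303, adjusted p = 0.002495), CCN1 by -1.46 (SE 0.239, adjusted p = 0.009661), NREP by -1.11 (adjusted p = 0.009661) and JUND by -1.33 (adjusted p = 0.01559). Also lower were NRG1, KLF6, FLOT2 and EHD2, and also higher were AKR1C3, EGR2, H2BC21, H2AC18 and RGPD6. Much of the averaged fall of some genes rests on the single combination library. In paclitaxel over DMSO, CCN1 was at -0.66, JUND at -0.67, FLOT2 at -0.39 and EHD2 at -0.44. In combination over enzastaurin the same genes were at -2.31, -2.09, -2.15 and -2.08. Enzastaurin raised 1 gene, RGPD6 (2.22, SE 0.325, adjusted p = 0.01407), whose sum with RGPD5 was at 0.04 and 0.03 in the 2 enzastaurin contrasts, and 702 genes had an unadjusted p under 0.05. These calls are fragile: with scaling by library size alone edgeR called 0 genes for either drug (361 for enzastaurin and 921 for paclitaxel at an unadjusted p under 0.05), and DESeq2 called 0 for enzastaurin (213 unadjusted) and 6 for paclitaxel.

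Set tests on that model gave a direction to several lists only with a preset correlation between genes. With paclitaxel, camera at a correlation of 0.01 gave NRF2 targets up (adjusted p = 1.074e-15), histones up (5.326e-12), S phase genes down (1.312e-11) and YAP targets down (1.736e-07). With enzastaurin it gave S phase genes down (1.506e-08), NRF2 targets up (2.012e-08), AP-1 genes down (2.075e-06) and YAP targets down (3.648e-06). In enzastaurin over DMSO alone the S phase list had a median of -0.02 (percentile 28.6) and the YAP list one of -0.07 (percentile 3.33), both in the middle 95%. None of these held when camera estimated the correlation (smallest adjusted p = 0.8218 for paclitaxel and 0.8348 for enzastaurin). Nor did they with fry, which asks whether a list moves one way (smallest adjusted p = 0.1536 and 0.09987). Both settings draw on 1 residual degree of freedom, and the estimated correlation was 1 for the S phase list. A list that fails them is therefore not shown to be unmoved. Of the NRF2 list, 2 genes passed for paclitaxel over all genes and 10 adjusted over the list alone; of the S phase list, 0 and 10; of the AP-1 list, 3 and 7; of the YAP list, 1 and 6.

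Paclitaxel shifted genes in a similar direction with and without enzastaurin, whereas the enzastaurin ratios had almost no relation between the 2 paclitaxel states. Across 11835 genes, paclitaxel over DMSO and combination over enzastaurin, which share no library, had a Pearson r of 0.199 and a Spearman rho of 0.325. For enzastaurin over DMSO against combination over paclitaxel, r was -0.00457 and rho 0.0373 across 11833 genes. Genes are not independent replicates, so no p is given. Passing the 2-fold rule upward in both paclitaxel contrasts were 21 genes, where 0.892 would be expected from independent lists, and downward 14, where 2.77 would be; in opposite directions were 6 higher with paclitaxel over DMSO (5.21 expected) and 4 lower (0.474 expected). For the enzastaurin contrasts 5 genes were shared upward and 5 downward, where 0.299 and 2.21 would be expected, and about as many passed in opposite directions, 5 higher with enzastaurin over DMSO (2.17 expected) and 4 lower (0.304 expected).

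**Figure D3:**
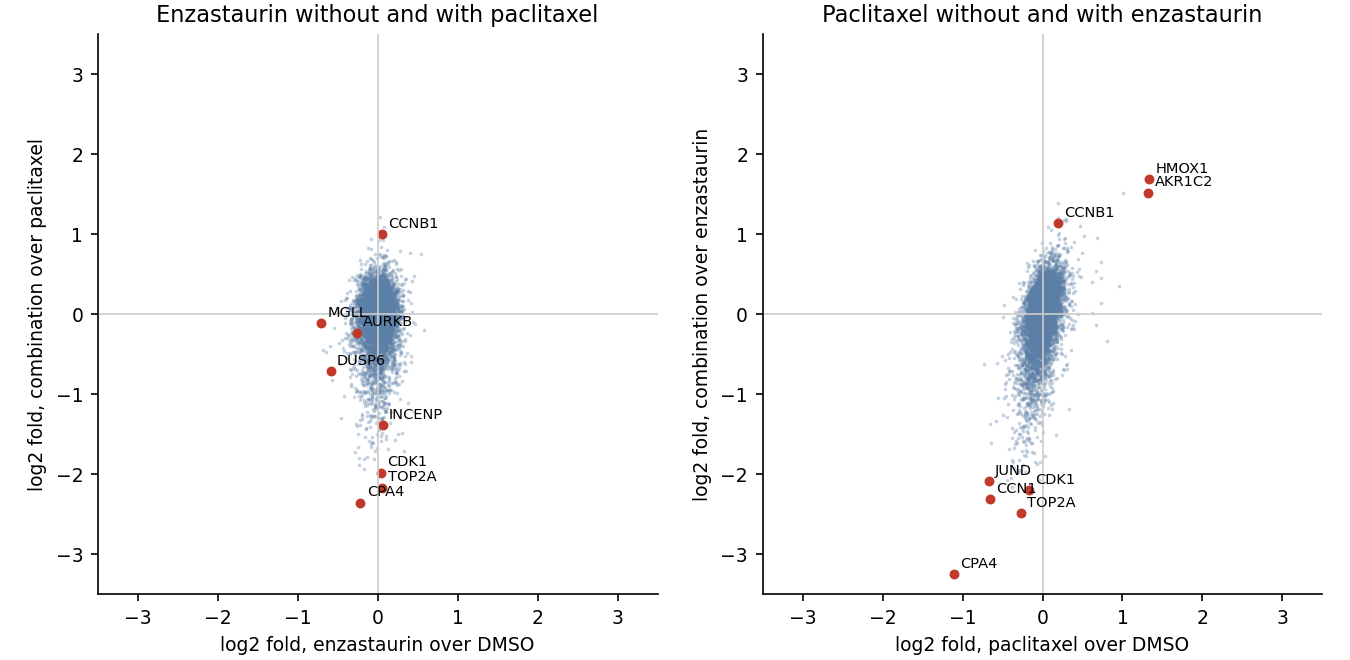
Log2 ratios of 6986 genes with a mean of at least 500 counts, with enzastaurin over DMSO against combination over paclitaxel on the left and paclitaxel over DMSO against combination over enzastaurin on the right; each point is a gene, and the labelled genes were picked by hand. Pearson r among these genes is 0.0495 on the left and 0.479 on the right.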

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

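Chosen only after the result was seen were the tests on mitotic genes (length and GC trend, effective length, share of mitotic cells), the correlation of the combination with the paclitaxel direction, and the ABCB1 level; thinning and the length and GC trend on the other patterns were also chosen after the data were seen, though before their own outcome was.

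The combination library stood apart from the 3 others, with 562 genes past the 2-fold rule against paclitaxel where enzastaurin alone had 105. Its lower depth alone would bring these counts within 1.5 times of each other once all libraries are thinned to its total, but 538 and 94 genes remained, a ratio of 5.72. Removal of the length and GC trend left 458 and 95 genes, a ratio of 4.82. With 1 library per condition, a difference of culture or library preparation and the effect of both drugs cannot be told apart for these genes.

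Mitotic genes moved apart in the combination, with CCNB1, CDC20 and AURKA higher and TOP2A, CDK1 and UBE2C lower than in paclitaxel. Of 67 measured members of the 3 mitosis lists and the S phase list, 25 were higher and 35 lower beyond their counting interval, and 98.3% of these (59 of 60) kept their side after the length and GC trend was removed; a first version on the 5 highest and 5 lowest members kept 10 of 10 and was replaced. Reads moved between isoforms of unlike length would change the effective length of these genes. Its median absolute shift was 0.0153 on the log2 scale and its largest 0.306, against a median absolute ratio of 0.508. Isoforms of similar length would leave effective length unchanged, so this check cannot exclude reads moved between those. A higher share of mitotic cells was predicted to raise the mitotic entry list together, but 4 of its 22 members passed the rule downward and 0 upward. Levels of these mRNAs in mitotic cells were not measured, and these values are the ones in which the pattern was seen. They therefore do not decide whether a higher share is the whole explanation or a part of it. A higher share, a drug response of individual mRNAs and a difference of the single combination culture all stay open. Lower new transcription was also considered and stays untested. Its test, a low AP-1 list (median -0.47), was dropped because that list was negative in all 5 contrasts, including enzastaurin over DMSO (-0.25).

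Genes with many counts continued in the paclitaxel direction when enzastaurin was added. Across 6986 genes with a mean of at least 500 counts, paclitaxel over DMSO and combination over paclitaxel had r = 0.325. The shared paclitaxel library alone pulls r below 0, to -0.497 in simulations without an effect (-0.513 to -0.479). The sign depends on the genes included, since over all 11837 tested genes r was -0.157 against a simulated -0.485. With the length and GC trend removed r was 0.345 among the abundant genes. Against lower ABCB1 mRNA in the combination as a source, ABCB1 was at 0.334 (0.290 to 0.378) in combination over paclitaxel. Both r values, 0.325 and -0.157, lie above the simulated ones, but the simulations held no effect of either drug. They also gave every library the same spread, with a simulated covariance of -0.0392 among the abundant genes. The log2 ratios of paclitaxel over DMSO had an SD of only 0.132 there, too narrow for a shared-library covariance of that size. The simulated r of -0.497 thus overstates the pull of the shared library, whose true size is not known. A paclitaxel effect alone, or a difference of the single combination culture, would also make r less negative. Whether enzastaurin adds to the paclitaxel response stays open. Each condition has 1 library, and the simulated spread (0.134) was fitted to the same 4 libraries.

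The remaining values are genes or lists past the 2-fold rule, or in the outer 5% of random lists, whose enzastaurin or paclitaxel ratios pointed in opposite directions with and without the other drug; none of these differences was tested, and each rests on 1 library per condition. In enzastaurin over DMSO and then in combination over paclitaxel, SMIM11A was at 4.28 and -4.41, SMIM11B at -2.90 and 3.11, CDRT4 at -4.14 (a bound) and 5.86 (3.30 to 11.19), and TVP23C-CDRT4 at 4.44 and -2.69. In the same contrasts INO80B-WBP1 was at -4.63 and 4.49 (both bounds), P3R3URF-PIK3R3 at 3.79 (1.79 to 6.90) and -4.67 (-10.01 to -2.09), GABRR2 at 2.35 and -1.54, and FAM187A at 1.33 and -2.00. The ribosomal protein list had medians of -0.06 and 0.26. In paclitaxel over DMSO and then in combination over enzastaurin, SMIM11A was at 4.29 and -4.40, SMIM11B at -2.94 and 3.07, CDRT4 at -5.89 (-11.22 to -3.35) and 4.10 (the latter a bound), and TVP23C-CDRT4 at 4.01 and -3.12. There INO80B-WBP1 was at -4.80 and 4.32 (both bounds), P3R3URF-PIK3R3 at 3.99 (2.03 to 7.09) and -4.46 (-9.82 to -1.86), POC1B-GALNT4 at 1.52 and -3.36, GABRR2 at 2.18 and -1.71, and FAM187A at 1.62 and -1.71. Summed with their partners in combination over paclitaxel, SMIM11A and SMIM11B were at 0.14, the CDRT4 locus at 0.29, INO80B with WBP1 at -0.20 and the PIK3R3 locus at 0.21. GALNT4 and POC1B summed were at 0.07 in paclitaxel over DMSO and 0.10 in combination over enzastaurin. GABRR2 and FAM187A were not summed with any other gene, so a shift of shared reads is not excluded for them.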

How the results depend on the processing

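Chosen after the data were seen were thinning to the smallest library, removal of the length and GC trend and the subset with a mean of at least 500 counts. Scaling by DESeq2 size factors or library size, thinning and trend removal kept every 2-fold count within 1.5 times of its reported value, and moved the share of higher genes by under 10 percentage points. Counts below are for enzastaurin over DMSO, paclitaxel over DMSO, combination over DMSO, combination over paclitaxel and combination over enzastaurin, in that order. A minimum of 100 counts gave 12, 26, 481, 307 and 441 genes, a fold limit of 1.5 gave 274, 321, 1979, 1545 and 1985, and FPKM with a pseudocount of 1 gave 21, 28, 311, 185 and 279, each by its own construction. FPKM with a pseudocount of 0.1 gave 66 and 71 for the single drugs. No count minimum gave 220 and 262 for the single drugs, and its splits into higher and lower were 278 and 714, 166 and 570, and 234 and 692 for the combination contrasts. The split was 4 and 8 for enzastaurin at a minimum of 100, and 14 and 14 for paclitaxel by FPKM with a pseudocount of 1.

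The additive model called 66 genes for enzastaurin (8 up and 58 down, where the reported 1 was up) and 346 for paclitaxel with no filter on low counts. It called 0 and 0 with library size alone (5.61 prior degrees of freedom in place of 19.1), 0 and 6 with DESeq2, and 0 and 3 with limma on log2(FPKM + 1). The cause of these differences was not tested. At an unadjusted p under 0.05 those settings gave, in the same order, 908, 361, 213 and 573 genes for enzastaurin and 1586, 921, 529 and 1111 for paclitaxel. The correlation of the paclitaxel contrasts was 0.325 by Spearman, 0.328 with a minimum of 100 counts and 0.479 with a mean of at least 500, a move of over 0.1; the cause was not tested. That of the enzastaurin contrasts changed sign around 0, between -0.00634 and 0.0495. AURKB ratios stayed within their counting intervals under every alternative run. Of 54 outer pairs of list and contrast, 44 kept their side without matching, 48 with FPKM and 41 with the trend removed, and 0 reversed. Depth limits many of the largest ratios: 8 of the 10 genes highest in enzastaurin over DMSO, 6 of 10 in paclitaxel over DMSO and 8 of 10 in combination over paclitaxel had under 100 counts; of the 10 lowest, 7, 7 and 2 did.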

Other observations

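Several further mRNAs, some of them members of lists described above, were lower in the combination library than in paclitaxel. All genes in this part beyond the 2 largest of each list were chosen after their values were seen. MCL1, the anti-apoptotic BCL2 family member, had 12742, 11754, 13931 and 4200 counts in DMSO, enzastaurin, paclitaxel and the combination, and was at -1.27 (-1.32 to -1.22) in combination over paclitaxel. BCL2L1, which encodes BCL-XL, was at -0.62 (-0.68 to -0.56) there, and PMAIP1, which encodes the MCL1 antagonist NOXA, was at 1.43 (0.98 to 1.90) in combination over DMSO. Of the 17 measured apoptosis regulators, 0 passed the rule upward and 1 downward in combination over paclitaxel (percentile 26.3). Over DMSO 1 passed it upward and 1 downward. TUBB was at -1.12 (-1.15 to -1.10), MAP1B at -1.11 (-1.19 to -1.02) and MYC at -0.79 (-0.84 to -0.74) in combination over paclitaxel. STARD4, a sterol carrier gene, was at -1.06 (-1.26 to -0.86) there.

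Of 17 measured genes of the integrated stress and unfolded protein response, 1 passed the 2-fold rule in combination over paclitaxel. That gene, CHAC1, a glutathione-degrading enzyme induced by ATF4, was at 1.37 (0.73 to 2.04), and PSAT1, a serine synthesis enzyme, which did not pass it, was at -0.69 (-0.83 to -0.54). The mesenchymal transcription factor gene TWIST2 was at -1.35 (-1.50 to -1.21) in combination over DMSO and the collagenase gene MMP1 at 1.59 (0.85 to 2.38), while 16 of 19 measured members of their list passed the rule in neither direction. Of the p53 targets, ZMAT3 was at -1.08 (-1.27 to -0.89) and DDB2 at -1.01 (-1.35 to -0.68) over DMSO. NFKBIA, the inhibitor of NF-kB, was at -0.99 (-1.09 to -0.88) in combination over paclitaxel. KDR, a receptor gene of endothelial cells, was at -1.75 (-2.37 to -1.17), and the lysosomal sialidase gene NEU1 at 0.82 (0.61 to 1.03).

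Among genes with a mean of at least 500 counts, a ranking chosen after the values were seen, enzastaurin over DMSO was highest for CDH6, at 0.58 (0.46 to 0.69), and AKR1C2, at 0.55 (0.47 to 0.63), and lowest for TGM2, at -0.68 (-0.82 to -0.54), and MGLL, at -0.70 (-0.87 to -0.54). In paclitaxel over DMSO, genes picked from the 15 highest by the same ranking were the fibroblast matrix gene DCN at 0.95, the growth factor receptor PDGFRA at 0.73 and TXNIP at 0.67. In combination over paclitaxel, picks from the 15 lowest were THBS1 at -1.78 (-1.83 to -1.74) and FBXO5, the inhibitor of the anaphase-promoting complex, at -1.71 (-1.91 to -1.50). Relative to the sum of both single-drug log2 ratios, 744 genes were off by 2-fold or more in the combination, with no test of the interaction. Unlike the counts under the 2-fold rule, this count used no counting interval. It includes genes with few counts and genes that share reads, so it cannot be set beside those counts.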
